A study of Homo sapiens with 24 samples.

How the data were processed

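The series measured RNA in 24 libraries of 3 prostate cancer cell lines treated with SP-2509, an inhibitor of the histone demethylase LSD1 that is known here by its code name, or with 0.1% DMSO as the vehicle. There were 8 groups of 3 libraries. C42B, PC3 and LNCaP cells were harvested 72 h after treatment, and LNCaP cells also after 24 h in an experiment with its own vehicle control. Per the labels' protocols the dose was 1 µM in C42B and LNCaP and 2 µM in PC3, C42B grew in medium with charcoal-stripped serum and the other two lines in medium with untreated serum, RNA was extracted with TRIzol and libraries were made with a stranded kit. Cells were plated at 250000 per well for C42B and PC3, 350000 for LNCaP at 72 h and 400000 for LNCaP at 24 h. Dose, medium and plating density therefore differed between some lines, and the run dates written in the names of the 72 h files between all. The labels describe wells plated in triplicate and do not say that the 3 libraries of a group came from separate experiments, so p-values here measure only the spread between these libraries, which may be technical.

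For 72 h the deposited files gave 1 value for each of 43497 RefSeq transcripts with a gene symbol. The unit is not written in them. The values were taken as FPKM because TopHat2 2.0.9 and Cufflinks 2.1.1 are named per the submitters' processing notes, with the hg19 build, and because the values had no negative numbers, were not whole and did not sum to the same total. Whether Cufflinks was told of the stranded kit is not given in the sources used here, so overlapping and antisense genes cannot be told apart in them. For 24 h the deposited files gave whole-number counts per Ensembl gene in unstranded, forward and reverse columns, as STAR 2.4.2a writes them, with the GRCh38 build per the submitters' processing notes. The annotation release is not given in the sources used here. Each file held 1 library.

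Transcript values of the 72 h libraries were summed to 23612 gene symbols, values under 1e-12 being set to 0. Symbols of 1730 small non-coding RNAs were left out because their lengths make FPKM unstable, which left 21882 symbols. These small RNAs held 3.22% to 7.77% of the summed FPKM per library. FPKM was tested with limma 3.58.1 (R 4.3.3) on log2(FPKM + 1) with an intensity trend, over genes at 1 FPKM or more in at least 3 libraries of the fit. Each line was fitted on its own 6 libraries. Differences between lines in the effect of treatment were tested as an interaction term in a fit of all 18 libraries. A fold change on the log2(FPKM + 1) scale understates the change of genes at low values. Exact zeros can be failed estimates: 2 to 5 genes per group were listed at 0 in a library beside another of the same group at 5 FPKM or more. Such genes are given per library, with no mean. FPKM does not state depth. For intronless genes, products of FPKM and length inside a preset window were taken as 1 fragment. Their median per library implied about 16.2 to 23.7 M fragments, with a median of 20.5 M over libraries. This used the 17 libraries with at least 5 such genes. The preset window bounded the depths that could be implied, so depth was not measured independently of it. This estimate assumed the full annotated length, and 147 of 184 such values lay within 10% of their library's median.

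At 24 h the reverse-strand column held 94.6% to 95.0% of the counts in the 2 stranded columns and was used. It held 12976585 to 18416847 counts in genes per library. The entries that name no gene (unmapped, multimapping, in no feature or ambiguous) made up 24.4% to 24.9% of all counts and were left out. Of 60498 gene identifiers, 56434 matched a symbol in the gene name table used here. The counts were tested with edgeR 4.0.16 (TMM normalisation, filterByExpr, quasi-likelihood F test). Levels are given as CPM. SE at 24 h is the fold change divided by the square root of the F statistic. No test was made across the 24 h and 72 h files, which differ in aligner, build, annotation and unit.

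All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison. A gene was called at an adjusted p below 0.05, with no minimum fold. FPKM and CPM are given as mean ± SD of n = 3 libraries, and log2 fold changes ± SE. The 28 gene lists held 463 genes and covered mitosis and kinetochore, DNA replication and E2F targets, homologous recombination repair, androgen response, MYC and ribosome biogenesis, p53 targets, ATF4 and the integrated stress response, endoplasmic reticulum chaperones, hypoxia and HIF targets, iron homeostasis, NRF2 targets, metallothioneins, sterol synthesis, fatty acid synthesis, interferon response, NF-kB and inflammatory cytokines, pluripotency, neuroendocrine genes, the LSD1 complex, epithelial junctions and keratins, mesenchymal genes, lysosome and autophagy, heat shock, the apoptosis BCL2 family, mitochondrially encoded genes, and markers of immune cells, fibroblasts and endothelium. The mitochondrially encoded genes are absent from the 72 h values. Lists with at least 5 tested genes were tested with camera in limma with a preset correlation of 0.01, again with the correlation estimated per list, and with fry. Whether a call held with an estimated correlation cannot be compared between single lines and interactions, whose fits differ in number of libraries. Camera compares a list with the other genes, while fry tests whether its genes move one way on balance.

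The genes named are 10 fixed genes, the 6 highest and 6 lowest log2 fold changes among called genes with a symbol, at least 5 FPKM or CPM in a group mean and no overlap between treated and control libraries, and up to 3 called members with the largest change of each list that passed. Across lines they are the 8 rises and 8 falls called in every line whose smallest change is largest, and for each interaction the 5 genes with the smallest adjusted p in each direction at a mean of at least 5 FPKM in a group. Some genes that this rule names are not reported here. Symbols are those in the files. Gene positions are given only for genes whose versioned Ensembl identifier in the 24 h files equals that of the GENCODE annotation of GRCh38 used here. No position is given for the 72 h values, whose build was not used here.

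The fits were tested on simulated data with 200 changed genes each, drawn at 72 h from genes with a mean of at least 5 FPKM. The 72 h fits recovered 61.2% to 88.1% of 1.25-fold changes, 91.0% to 100% of 1.5-fold changes and 100% of 2-fold changes, and 2.76% to 6.34% of the calls were unchanged genes. At 24 h edgeR recovered 58.2%, 77.6% and 84.8% of these folds, with 5.16% of calls unchanged. The interaction fits recovered 55.2% to 62.7% of 1.25-fold, 94.0% to 97.0% of 1.5-fold and 95.5% to 98.5% of 2-fold differences. Their share of unchanged genes among the calls was 17.9% for PC3 against LNCaP, 9.68% for C42B against LNCaP and 5.00% for PC3 against C42B. In these simulations the share passed the 0.05 threshold for the interactions against LNCaP. It also passed it in the fits of C42B (6.34%), LNCaP at 72 h (6.15%) and LNCaP at 24 h (5.16%). Only 200 genes were changed there, while 4698 to 9701 were called in the real interactions. The shares therefore cannot be carried over to the real counts, which may still hold more false calls than the threshold implies. In the simulated C42B libraries a list of genes given 2-fold rises passed camera, and 0 of 20 random lists did. Simulated genes were drawn independently, so this does not test the preset correlation for lists whose genes vary together.

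The design, the tests, the named-gene rule, the lists and most alternatives were fixed before the data were examined. Those alternatives were another pseudocount, no filter on low values, median-ratio scaling or DESeq2 1.42.0 size factors, DESeq2 as the test, unstranded counts, limma without trend, fits on other sets of libraries, a minimum fold, an estimated correlation, the replicate number as a block and leaving out each library. Chosen after seeing the data were leaving out the small non-coding RNAs and setting the smallest values to 0, and, as alternatives, zeros taken as missing, small non-coding RNAs kept, the split of calls under the other scaling, other scaling and left-out libraries for the shared calls, and the gene families of the last part. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.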

Results

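RNA was measured in 3 prostate cancer cell lines after treatment with SP-2509 or vehicle. LNCaP is an androgen-sensitive line from a lymph node metastasis, C42B is a castration-resistant line derived from LNCaP, and PC3 comes from a bone metastasis. Each of the 8 groups held 3 libraries. The 24 h LNCaP libraries held 12976585 to 18416847 counts in genes. The 72 h libraries give FPKM, which state no depth, and 12070 to 12402 genes per library were at 1 FPKM or more. Treated libraries separated from control libraries along the first principal component in each comparison, which held 93.0% of the variance in C42B, 90.4% in PC3, 88.8% in LNCaP at 72 h and 60.1% in LNCaP at 24 h. Below, n = 3 libraries per condition, levels are given as mean ± SD and log2 fold changes as estimate ± SE.

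The first comparison asked which genes changed in C42B cells after 72 h of 1 µM SP-2509. GDF15, a secreted stress-response protein, rose from 56.4 ± 2.93 to 977 ± 19.8 FPKM, and CDKN1A, which encodes the cell cycle inhibitor p21, rose from 25.3 ± 0.573 to 433 ± 5.86 FPKM, log2 fold changes of 4.09 ± 0.040 (limma adjusted p = 5.1e-11) and 4.05 ± 0.028 (limma adjusted p = 8.6e-12). PLK1, a mitotic kinase, fell from 63.2 ± 1.12 to 4.96 ± 0.604 FPKM (-3.43 ± 0.064), and the kinetochore motor gene CENPE fell from 13.2 ± 0.228 to 1.95 ± 0.0940 FPKM (-2.26 ± 0.043). KDM1A, which encodes LSD1 itself, fell from 31.0 ± 0.709 to 19.1 ± 0.527 FPKM (-0.67 ± 0.034).

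All 34 genes of the mitosis and kinetochore list fell in C42B, with a mean log2 fold change of -2.18 (camera adjusted p = 8.6e-15, adjusted p = 0.10 with an estimated correlation). Among them were KIF20A, a kinesin of cytokinesis (-3.04 ± 0.086), CDC20, an activator of the anaphase-promoting complex (-3.04 ± 0.063), the spindle gene HMMR (-2.74 ± 0.051) and the kinetochore gene NDC80 (-2.68 ± 0.084). All 30 DNA replication and E2F targets fell (mean -1.47, camera adjusted p = 2.3e-12, adjusted p = 0.10 with an estimated correlation). Among them were the replication factor MCM10 (-2.23), the DNA methylation maintenance gene UHRF1 (-2.03) and thymidine kinase TK1 (-1.98). All 16 genes of homologous recombination repair fell (mean -1.03, camera adjusted p = 7.2e-06, adjusted p = 0.14 with an estimated correlation). Among them were EXO1 (-1.68), RAD51AP1 (-1.51) and XRCC2 (-1.44). Of the MYC and ribosome biogenesis list 20 of 21 genes fell and 1 rose (mean -0.59, camera adjusted p = 1.5e-05, adjusted p = 0.13 with an estimated correlation). There were falls of NOP56 (-1.14), nucleolin gene NCL (-1.06), SRM (-1.05) and MYC itself (-0.56 ± 0.038).

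In the sterol synthesis list of C42B 18 of 19 genes fell and 1 rose (mean -1.02, camera adjusted p = 2.7e-06, adjusted p = 0.10 with an estimated correlation). There were falls of INSIG1, a sensor of sterol levels (-2.08), and EBP (-1.51). In fatty acid synthesis 10 of 11 genes fell and 1 rose (mean -1.29, camera adjusted p = 1.3e-04, adjusted p = 0.34 with an estimated correlation). Among them were the desaturase FADS2 (-2.62), the elongase ELOVL6 (-2.37) and fatty acid synthase FASN, which fell from 228 ± 5.53 to 61.6 ± 1.74 FPKM.

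Among the rises in C42B were all 22 p53 targets (mean 1.58, camera adjusted p = 1.3e-14, adjusted p = 0.10 with an estimated correlation), TP53I3 among them (2.15). In the list of ATF4 and the integrated stress response 21 of 23 genes rose, 1 fell and 1 did not pass (mean 0.99, camera adjusted p = 1.3e-10, adjusted p = 0.10 with an estimated correlation). ATF3 was at 2.92, the transcription factor gene DDIT3 (CHOP) at 2.87 ± 0.036 and SESN2 at 1.86. Of lysosome and autophagy genes 12 of 14 rose and 2 fell (mean 0.42, camera adjusted p = 1.1e-04, adjusted p = 0.22 with an estimated correlation). Among them were the autophagosome genes MAP1LC3B (1.17) and GABARAPL1 (1.07) and the autophagy receptor SQSTM1 (0.95). In the apoptosis BCL2 family 8 of 11 rose and 3 fell (mean 0.73, camera adjusted p = 0.0026, adjusted p = 0.10 with an estimated correlation), and the rises of BMF (2.30), BBC3 (2.07) and HRK (1.07) are of genes known to promote apoptosis. Members that moved against their lists were the nucleolar gene GNL3 (0.29), the serine synthesis gene PHGDH (-0.25), the sterol desaturase SC5DL (0.50), the elongase ELOVL5 (0.09), the lysosomal genes GLA (-0.91) and MCOLN1 (-0.50), and BID (-0.29), MCL1 (-0.21) and BAK1 (-0.14) of the BCL2 family. The counts in these 10 lists were the same when adjusted over the list alone. The largest single rises outside these lists were those of GPNMB, a transmembrane glycoprotein found in lysosomes (5.06 ± 0.055), DIO3, which inactivates thyroid hormone (4.65 ± 0.050), C11orf92 (4.32 ± 0.036) and the nitric oxide synthase gene NOS3 (3.58 ± 0.053). KLK3, which encodes prostate-specific antigen, fell by 0.87 ± 0.042, while ZNF217 rose by 0.75 ± 0.029, the transferrin receptor gene TFRC by 0.49 ± 0.033 and heme oxygenase HMOX1 by 0.49 ± 0.045.

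Lists that did not pass camera in C42B were iron homeostasis (adjusted p = 0.086), hypoxia and HIF targets (0.20), metallothioneins (0.31), heat shock (0.31), interferon response (0.31), epithelial junctions and keratins (0.33), endoplasmic reticulum chaperones (0.37), the LSD1 complex (0.63), NRF2 targets (0.69) and androgen response (0.72). The androgen list had a median and mean of -0.04 beside a test direction of up, and the interferon list a median of -0.02 and a mean of 0.21. With fry 19 of 20 lists passed in C42B, among them endoplasmic reticulum chaperones (fry adjusted p = 1.5e-06). Of these chaperones 8 were higher, 8 lower and 1 not called (median 0.0007, mean 0.14), so they did not share a direction. In total 9335 of 12417 genes tested were called by limma, 3744 higher and 5591 lower, of which 329 and 462 changed at least 2-fold, and treated and control libraries did not overlap for 77.9% of genes, against 10% by chance. With median-ratio scaling the calls in C42B were 4287 higher and 5064 lower. SEPT7 was called, but 2 of its treated libraries were listed at 0 FPKM beside 21.32 FPKM in the other and 27.48, 27.66 and 27.86 FPKM in the controls. With zeros taken as missing only 1 treated library is left, so no test of SEPT7 is given for that case. With zeros kept the call was lost without treated replicate 1 (adjusted p = 0.055), without treated replicate 2 (0.054) or without the filter on low values (0.051).

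The same question was asked of PC3 cells, given 2 µM SP-2509 for 72 h. The inflammatory chemokine gene IL8 rose from 7.64 ± 0.751 to 288 ± 11.2 FPKM (5.07 ± 0.061, limma adjusted p = 2.5e-11), and ADM, which encodes the vasodilator peptide adrenomedullin, from 3.80 ± 0.325 to 60.4 ± 2.83 FPKM (3.68 ± 0.058, limma adjusted p = 7.1e-11). MYC rose from 66.4 ± 3.98 to 284 ± 15.1 FPKM (2.08 ± 0.054) and CDKN1A from 6.77 ± 0.106 to 30.6 ± 0.998 FPKM (2.02 ± 0.043). PHACTR3, a regulator of protein phosphatase and actin, fell from 58.2 ± 3.94 to 3.06 ± 0.285 FPKM (-3.87 ± 0.064).

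All 22 hypoxia and HIF targets rose in PC3, with a mean of 1.43 (camera adjusted p = 3.6e-13, and 0.024 with an estimated correlation). Among them were NDRG1 (2.77 ± 0.058) and the glucose transporter SLC2A1 (1.85 ± 0.049). All 13 NF-kB and inflammatory cytokine genes rose (mean 1.89, camera adjusted p = 3.1e-08, and 0.036 with an estimated correlation). Among them were TNFAIP3, which restrains NF-kB signalling (3.28 ± 0.048), and BIRC3 (2.35 ± 0.054). All 7 genes of the metallothionein list, metal-binding proteins and the zinc transporter SLC30A1, rose (mean 1.43, camera adjusted p = 7.4e-04, adjusted p = 0.10 with an estimated correlation). MT1X was at 2.90, MT2A at 2.09 and MT1G at 1.87. Values of single metallothioneins are uncertain because their sequences are close. In the list of ATF4 and the integrated stress response 17 of 23 genes rose and 3 fell (mean 0.93, camera adjusted p = 1.9e-05, adjusted p = 0.072 with an estimated correlation). Among them were ATF3 (3.13), the phosphatase subunit PPP1R15A (2.48) and DDIT3 (2.29 ± 0.050). Of lysosome and autophagy genes 10 of 13 rose and 1 fell (mean 0.51, camera adjusted p = 7.4e-04, adjusted p = 0.27 with an estimated correlation). SQSTM1 was at 1.46, MAP1LC3B at 0.93 and the sialidase NEU1 at 0.74.

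In the mesenchymal list 9 of 12 genes rose and 2 fell in PC3 (mean 0.60, camera adjusted p = 0.0021, adjusted p = 0.27 with an estimated correlation): the transcription factor SNAI2 rose (2.78), while the matrix protein SPARC fell (-1.82). The apoptosis BCL2 family had 7 rises and 2 falls among 11 genes (mean 0.53, camera adjusted p = 0.048, adjusted p = 0.37 with an estimated correlation). The call was also lost with a pseudocount of 0.1 (camera adjusted p = 0.052). There were rises of BCL2A1, known to oppose apoptosis (1.32), and of BIK (1.28) and BBC3 (1.10), known to promote it. Mitosis and kinetochore genes fell in 31 of 34 cases and rose in 1 (mean -0.49, camera adjusted p = 2.1e-07, adjusted p = 0.27 with an estimated correlation). CENPE was at -1.16 ± 0.052, CCNB1 at -1.02 and DLGAP5 at -0.95. Fatty acid synthesis had 10 falls and 1 rise among 11 genes (mean -0.53, camera adjusted p = 0.0015, adjusted p = 0.26 with an estimated correlation), ACACA, FASN and FADS2 falling by 1.16, 1.10 and 0.99. Besides SPARC, members that moved against their lists were the cystine transporter SLC7A11 (-1.15), SLC7A5 (-0.24), SHMT2 (-0.12), fibronectin FN1 (-0.40), ATP6V1H (-0.18), UBE2C (0.14), ACSS2 (0.11), BAK1 (-0.19) and BCL2L1 (-0.19). The counts in these 9 lists were the same when adjusted over the list alone. Other large rises were those of the cytokine gene CSF2 (3.93 ± 0.094), the calcium-binding protein S100P (3.78 ± 0.076), SLAMF9 (3.73 ± 0.055) and RGCC (3.42 ± 0.094). The largest other falls were those of RASL11A (-3.04 ± 0.052), the long non-coding RNA LINC00261 (-3.02 ± 0.048), the mucin MUC5B (-2.54 ± 0.096) and the near-identical serpins SERPINB3 (-3.28 ± 0.074) and SERPINB4 (-2.69 ± 0.071), whose separate values are uncertain. TFRC rose by 1.39 ± 0.051 and HMOX1 by 0.74 ± 0.087, ZNF217 fell by 0.49 ± 0.038, and KDM1A did not pass the test (-0.01 ± 0.036, limma adjusted p = 0.72). KLK3 lay below the filter in PC3.

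Lists that did not pass camera in PC3 were interferon response (adjusted p = 0.070), p53 targets (0.083), epithelial junctions and keratins (0.11), iron homeostasis (0.18), heat shock (0.18), the LSD1 complex (0.63), NRF2 targets (0.65), DNA replication and E2F targets (0.68), androgen response (0.69), homologous recombination repair (0.69), endoplasmic reticulum chaperones (0.73), sterol synthesis (0.73) and MYC and ribosome biogenesis (0.77). The median and mean differed in sign for the MYC list (-0.09 and 0.02, test down), for chaperones (-0.11 and 0.004, test down) and for NRF2 targets (-0.02 and 0.11, test up). With fry 20 of 22 lists passed. Limma called 9104 of 12511 genes tested, 4206 higher and 4898 lower, of which 417 and 175 changed at least 2-fold, and 75.1% of genes had no overlap between treated and control libraries. With median-ratio scaling the calls in PC3 were 4884 higher and 4099 lower, so which direction held more genes depended on the scaling.

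In LNCaP cells the comparison at 72 h used 1 µM SP-2509. DIO3 rose from 4.70 ± 0.653 to 304 ± 6.06 FPKM (5.75 ± 0.077, limma adjusted p = 2.4e-09) and IGFBP3, which binds insulin-like growth factors, from 4.93 ± 0.164 to 82.7 ± 0.816 FPKM (3.82 ± 0.040, limma adjusted p = 4.8e-10). KLK3 fell from 1550.4 ± 27.3 to 637 ± 5.69 FPKM (-1.28 ± 0.043). CDKN1A rose from 56.5 ± 1.62 to 419.6 ± 14.7 FPKM (2.87 ± 0.044), and PLK1 fell from 33.6 ± 0.370 to 2.63 ± 0.234 FPKM (-3.255 ± 0.054).

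All 34 mitosis and kinetochore genes fell in LNCaP at 72 h, with a mean of -2.41 (camera adjusted p = 9.3e-21, adjusted p = 0.080 with an estimated correlation). Among them were CDC20 (-3.15 ± 0.044), HMMR (-3.02 ± 0.087), CENPE (-2.53 ± 0.052), DLGAP5 (-2.91 ± 0.086) and KIF20A (-2.89 ± 0.047). All 30 DNA replication and E2F targets fell (mean -1.44, camera adjusted p = 2.3e-15, adjusted p = 0.061 with an estimated correlation). TK1 was at -2.11, UHRF1 at -1.97 and MCM10 at -1.97. All 16 genes of homologous recombination repair fell too (mean -1.13, camera adjusted p = 1.1e-07, adjusted p = 0.27 with an estimated correlation). RAD51AP1 was at -1.80, BRCA1 at -1.76 and EXO1 at -1.69. Of the MYC and ribosome biogenesis list 17 of 21 genes fell and 1 rose (mean -0.48, camera adjusted p = 3.4e-05, adjusted p = 0.13 with an estimated correlation). Among them were NOP56 (-0.88), MYC (-0.82 ± 0.059) and NCL (-0.79). The androgen response list had 17 falls and 3 rises among 23 genes (mean -0.49, camera adjusted p = 4.4e-04, adjusted p = 0.27 with an estimated correlation). There were falls of NCAPD3 (-1.19) and PPAP2A (-1.09) beside KLK3, and 18 falls adjusted over the list alone. Sterol synthesis had 18 falls and 1 rise among 19 genes (mean -0.56, camera adjusted p = 5.1e-05, adjusted p = 0.29 with an estimated correlation): INSIG1 fell (-1.246) and SC5DL rose (0.99). Fatty acid synthesis had 10 falls and 1 rise among 11 genes (mean -0.94, camera adjusted p = 7.5e-05, adjusted p = 0.16 with an estimated correlation). FADS2 was at -2.14, ELOVL6 at -1.38 and FASN at -1.38.

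Of p53 targets 21 of 22 rose in LNCaP at 72 h and 1 did not pass (mean 1.13, camera adjusted p = 2.3e-14, adjusted p = 0.16 with an estimated correlation), TP53I3 at 2.37 and GDF15 at 2.35 ± 0.050. The ATF4 and integrated stress response list had 11 rises and 7 falls among 23 genes, and 13 rises adjusted over the list alone (mean 0.52, camera adjusted p = 0.0012, adjusted p = 0.27 with an estimated correlation). ATF3 was at 3.17 ± 0.051, DDIT3 at 2.69 ± 0.049 and PPP1R15A at 1.86. Lysosome and autophagy genes rose in 11 of 14 cases and fell in 2, or 3 adjusted over the list alone (mean 0.51, camera adjusted p = 8.7e-05, adjusted p = 0.29 with an estimated correlation). SQSTM1 was at 1.51, MAP1LC3B at 1.44 and NEU1 at 0.97. NRF2 targets, genes of the antioxidant response, had 8 rises and 1 fall among 14 (mean 0.44, camera adjusted p = 6.9e-04, adjusted p = 0.27 with an estimated correlation). Among them were AKR1C1 (1.55), the ferritin light chain FTL (1.02) and HMOX1 (0.94 ± 0.073). Interferon response genes rose in 8 of 14 cases (mean 0.32, camera adjusted p = 0.0012, adjusted p = 0.27 with an estimated correlation). ISG20 was at 0.98, OAS1 at 0.97 and IRF7 at 0.74. Heat shock genes rose in 7 of 12 cases and fell in 2 (mean 0.27, camera adjusted p = 0.0075, adjusted p = 0.28 with an estimated correlation). HSPA4L was at 0.62, HSPA1A at 0.92 and HSPA1B at 0.89, and the separate values of the last pair are uncertain because their sequences are near-identical.

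The apoptosis BCL2 family had 5 rises and 2 falls among 12 genes in LNCaP at 72 h, with 1 fall adjusted over the list alone (mean 0.39, camera adjusted p = 0.0097, adjusted p = 0.29 with an estimated correlation), and rises of BBC3 (1.28), BMF (1.245) and HRK (0.89). Hypoxia and HIF targets had 10 rises and 6 falls among 21 (median 0.06, mean 0.28, camera adjusted p = 0.021, adjusted p = 0.55 with an estimated correlation): the collagen hydroxylase P4HA2 (1.87) and the angiogenic factor VEGFA (1.87) rose, while lactate dehydrogenase LDHA fell (-0.997). For the passing lists not given a second count here, the counts adjusted over the list alone were the same. Members that fell against rising lists included the amino acid synthesis genes PHGDH (-0.43), PSAT1 (-0.35) and ASNS (-0.17), the glycolytic gene PGK1 (-0.55), thioredoxin TXN (-0.46), GLA (-0.79), DNAJA1 (-0.24) and MCL1 (-0.24). KLK4 (0.42), ALDH1A3 (0.62) and HERC3 (0.34) rose against the androgen list, GNL3 (0.18) against the MYC list and ELOVL5 (0.19) against fatty acid synthesis. Other large rises were GPNMB (3.80 ± 0.039), the small heat shock protein CRYAB (3.12 ± 0.059) and LCN2, which binds iron-carrying siderophores (2.96 ± 0.077). KDM1A fell by 0.66 ± 0.060, TFRC rose by 0.50 ± 0.083, and ZNF217 did not pass (-0.03 ± 0.044, limma adjusted p = 0.54).

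Lists that did not pass camera in LNCaP at 72 h were the LSD1 complex (adjusted p = 0.16), iron homeostasis (0.26), mesenchymal genes (0.45), endoplasmic reticulum chaperones (0.56), epithelial junctions and keratins (0.79) and metallothioneins (0.98), and for the last pair the median and mean were negative beside a test direction of up. With fry 20 of 21 lists passed. Limma called 7705 of 12288 genes tested, 2996 higher and 4709 lower, of which 231 and 334 changed at least 2-fold, and 68.1% of genes had no overlap between treated and control libraries. With median-ratio scaling the calls were 3670 higher and 3998 lower, so most of the excess of falls depended on the scaling. SEPT7 was called here too, with 2 treated libraries listed at 0 FPKM beside 17.53 FPKM in the other and 20.18, 20.38 and 20.36 FPKM in the controls, which again leaves 1 treated library when zeros are taken as missing. With zeros kept the call was lost without control replicate 1, 2 or 3 (adjusted p = 0.064, 0.066 and 0.059), without treated replicate 2 (0.076) or 3 (0.051), and without the filter (0.073). At 72 h the neuroendocrine, pluripotency, immune cell, fibroblast and endothelial lists had fewer than 5 tested genes in every line, as had the mesenchymal list in C42B and the NF-kB list in C42B and LNCaP, and these were not tested.

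**Figure D1:**
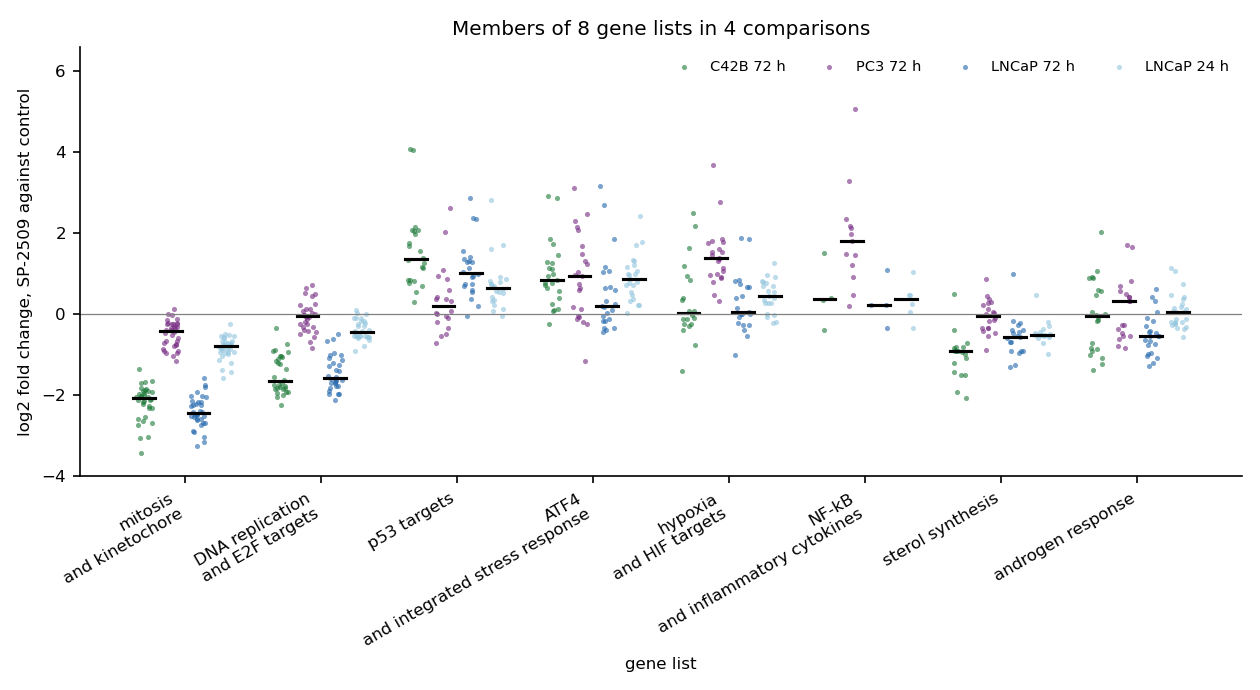
Log2 fold change of each member of 8 gene lists (points) and the list's median (black bar) after SP-2509 against control, in C42B, PC3 and LNCaP at 72 h and LNCaP at 24 h. Mitosis and kinetochore genes had a median of -2.06 in C42B, -0.41 in PC3, -2.44 in LNCaP at 72 h and -0.79 at 24 h, and hypoxia and HIF targets had a median of 1.38 in PC3.

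The calls of the 3 lines were then set side by side, over 10988 genes tested in each. IGFBP3 rose in C42B (3.07), PC3 (3.256) and LNCaP (3.82), and ATF3, a stress-induced transcription factor, by 2.92, 3.13 and 3.17. S100P rose by 3.35, 3.78 and 2.91, the DNA damage-inducible gene GADD45A by 2.38, 2.24 and 2.21, and the epithelial transcription factor ELF3 by 2.06, 2.00 and 1.82, in the same order of lines, and GDF15, DDIT3 and CDKN1A completed the 8 rises with the largest smallest change. Falls were shared by the proliferation marker MKI67 (-2.55, -1.20 and -2.69), cyclin B1 (CCNB1; -2.54, -1.02 and -2.59) and the cell cycle inhibitor CDKN2C (-1.92, -1.36 and -2.09). The nuclear envelope gene TMPO (-1.66, -1.252 and -1.86) and the splicing protein HNRNPM (-1.15, -1.01 and -1.05) also fell, as did CENPE and FASN. BCYRN1 fell too (-2.35, -1.59 and -1.88), but it is a short RNA related to Alu repeats and its values are uncertain.

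Of these genes 1067 were called higher in every line, where independent lists would share 246, and 1991 were called lower, where 810.2 would be shared. At a change of at least 2-fold 41 were higher and 11 lower in every line. C42B and LNCaP were called in the same direction for 5752 genes and in opposite directions for 257, and their log2 fold changes correlated across genes with r = 0.87 (rho = 0.83). For C42B and PC3 these counts were 3987 and 2150 (r = 0.32, rho = 0.27), and for PC3 and LNCaP 3612 and 1547 (r = 0.33, rho = 0.30). Genes are not independent replicates, so these correlations have no p-value.

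**Figure D2:**
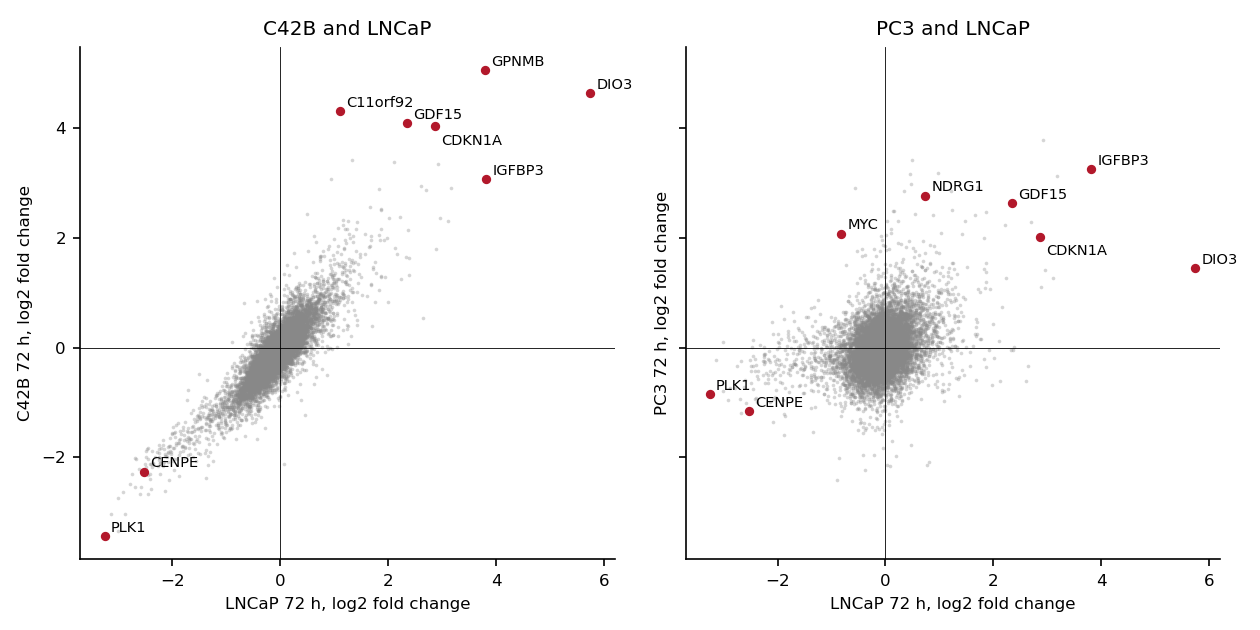
Log2 fold change per gene at 72 h in C42B (left) and PC3 (right) against that in LNCaP, with named genes in red. The fold changes correlated across genes with r = 0.87 for C42B and LNCaP and r = 0.33 for PC3 and LNCaP.

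Whether the response differed between lines was tested as an interaction, each value being the log2 fold change in the first line minus that in the second. A higher response is therefore a more positive change, not a stronger one, and can be a smaller fall. Mitosis and kinetochore genes had a mean of -0.49 in PC3 and -2.41 in LNCaP, and DNA replication and E2F targets -0.06 and -1.44. Sterol synthesis genes had a mean of -1.02 in C42B and -0.56 in LNCaP, so their lower response in C42B was a larger fall. Against LNCaP, the response of PC3 was higher for IL8 (4.89 ± 0.080, limma adjusted p = 2.9e-16), the epidermal caspase CASP14 (2.72 ± 0.047), TNFAIP3 (3.06 ± 0.057), PODXL (2.30 ± 0.046) and the spindle gene NUSAP1 (2.49 ± 0.052), and MYC differed by 2.90 ± 0.080. IL8, CASP14 and TNFAIP3 lay below the filter in LNCaP, with IL8 at 0.138 ± 0.0536 FPKM in controls and 0.286 ± 0.0631 FPKM in treated libraries, so their values mainly restate the rise in PC3. It was lower for LINC00261 (-3.03 ± 0.056, limma adjusted p = 5.6e-16), PHACTR3 (-3.84 ± 0.073), GALNT10 (-2.39 ± 0.046), the collagen COL2A1 (-2.43 ± 0.047) and NBPF1 (-2.25 ± 0.047), a member of a family of close copies whose value is uncertain. LINC00261, PHACTR3 and COL2A1 lay below the filter in LNCaP and mainly restate the fall in PC3. The response of all 34 mitosis and kinetochore genes (mean difference 1.92, camera adjusted p = 1.1e-21, and 0.0069 with an estimated correlation) and all 30 DNA replication and E2F targets (1.38, camera adjusted p = 4.4e-16, and 0.0030) was higher in PC3, as it was for 12 of 13 NF-kB and inflammatory cytokine genes (1.73, camera adjusted p = 2.1e-07, and 0.0019) and 6 of 7 genes of the metallothionein list (1.57, camera adjusted p = 0.0017, and 0.031). These counts were the same adjusted over the list alone. Only 4 of the 13 NF-kB genes, 5 of the 7 metallothionein list and 5 of the 12 mesenchymal genes passed the filter in LNCaP, and for the others the difference mainly restates the change in PC3. Another 10 lists passed camera but not with an estimated correlation: homologous recombination repair (1.08, adjusted p = 2.1e-07 and 0.063 with an estimated correlation), hypoxia and HIF targets (1.14, 2.1e-07 and 0.063), p53 targets (-0.80, 3.9e-07 and 0.063), MYC and ribosome biogenesis (0.50, 1.5e-04 and 0.063), androgen response (0.59, 4.2e-04 and 0.11), heat shock (-0.54, 0.0010 and 0.063), sterol synthesis (0.48, 0.0014 and 0.15), mesenchymal genes (0.54, 0.0092 and 0.12, also lost with a pseudocount of 0.1 at 0.21), fatty acid synthesis (0.41, 0.020 and 0.28) and ATF4 and the integrated stress response (0.40, 0.033 and 0.27). The tests called 9072 of 13987 genes, 4911 with a higher and 4161 with a lower response in PC3.

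C42B differed less from LNCaP, with 4698 genes called, 2156 higher and 2542 lower. The response of C42B was higher for C11orf92 (3.219 ± 0.059, limma adjusted p = 1.8e-15), the sulfotransferase CHST2 (2.47 ± 0.063), thrombospondin THBS1 (1.95 ± 0.052), the calcitonin gene CALCA (2.32 ± 0.065), lipoprotein lipase LPL (1.64 ± 0.050), CDKN1A (1.17 ± 0.047) and ZNF217 (0.78 ± 0.047). CHST2, CALCA and LPL lay below the filter in LNCaP, so their values mainly restate the rise in C42B. It was lower for the peptidase THOP1 (-1.36 ± 0.052, limma adjusted p = 2.4e-11), myosin light chain kinase MYLK (-2.19 ± 0.098), RAP2B (-1.30 ± 0.059), NUCB2 (-0.85 ± 0.040) and the RNA-binding protein gene HNRPDL (-0.70 ± 0.036). With camera and also with an estimated correlation the response was higher in C42B for the lists of ATF4 and the integrated stress response (17 of 23 genes higher, 2 lower, mean difference 0.46, adjusted p = 4.0e-09 and 0.020), p53 targets (16 of 22, 0.45, 4.8e-09 and 0.037), androgen response (16 of 24, 0.44, 3.3e-08 and 0.021) and endoplasmic reticulum chaperones (12 of 17, 0.27, 8.7e-07 and 0.021). It was lower on the same terms for sterol synthesis (17 of 20, -0.44, 9.7e-10 and 0.020), NRF2 targets (12 of 15, -0.49, 4.2e-07 and 0.020) and heat shock (8 of 12, -0.45, 3.0e-06 and 0.020). Adjusted over the list alone these counts were 18, 17, 16 and 13 higher and 18, 13 and 9 lower. Mitosis and kinetochore (0.23, adjusted p = 4.1e-06 and 0.12 with an estimated correlation), fatty acid synthesis (-0.35, 5.0e-06 and 0.051), mesenchymal genes (0.20, 0.012 and 0.12), MYC and ribosome biogenesis (-0.11, 0.032 and 0.27), the apoptosis BCL2 family (0.25, 0.044 and 0.12) and metallothioneins (-0.32, 0.049 and 0.12) passed camera only, and the last pair also lost their calls with a pseudocount of 0.1 (0.052 and 0.051). Of the 12 mesenchymal genes only 3 passed the filter in C42B and 5 in LNCaP. KLK3 differed by 0.42 ± 0.15 (limma adjusted p = 0.042), a call that was lost in 11 of the 12 fits without a library (adjusted p = 0.053 to 0.090) and kept without C42B control replicate 3. These fits pool the spread over every line, and KLK3 lay at 0.117 to 0.791 FPKM in the PC3 libraries. The call was kept in the fit on the C42B and LNCaP libraries alone. MYC differed by 0.26 ± 0.080 (limma adjusted p = 0.020), a call lost without C42B treated replicate 1 (0.051) or LNCaP control replicate 1 (0.056).

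Between PC3 and C42B 9701 genes were called, 5358 with a higher and 4343 with a lower response in PC3. It was higher for IL8 (5.11 ± 0.080, limma adjusted p = 7.3e-17), TNFAIP3 (3.33 ± 0.057), CASP14 (2.71 ± 0.047), MYC (2.64 ± 0.080) and the near-identical keratins KRT81 (3.03 ± 0.067) and KRT86 (2.64 ± 0.060), whose separate values are uncertain. IL8, TNFAIP3, CASP14, KRT81 and KRT86 lay below the filter in C42B, so their values mainly restate the rise in PC3. It was lower for GPNMB (-5.14 ± 0.096, limma adjusted p = 3.1e-16), C11orf92 (-4.46 ± 0.059), PHACTR3 (-3.90 ± 0.073), CHST2 (-3.49 ± 0.063), LINC00261 (-3.03 ± 0.056) and CDKN1A (-2.02 ± 0.047). GPNMB and C11orf92 lay below the filter in PC3 and PHACTR3 and LINC00261 in C42B, so these values mainly restate the change in the other line. The lists that passed camera and also held with an estimated correlation were mitosis and kinetochore (34 of 34 genes higher, mean difference 1.69, adjusted p = 2.0e-17 and 0.016), DNA replication and E2F targets (29 of 30, 1.42, 2.8e-14 and 0.0049), p53 targets (21 of 22 lower, -1.247, 6.6e-12 and 0.022), NF-kB and inflammatory cytokines (12 of 13 higher, 1.72, 2.8e-06 and 0.0043) and metallothioneins (6 of 7 higher, 1.89, 0.0017 and 0.022), with the same counts adjusted over the list alone. Only 4 of the NF-kB genes and 5 of the metallothionein list passed the filter in C42B, and for the others the difference mainly restates the change in PC3. Homologous recombination repair (0.99, adjusted p = 2.2e-06 and 0.085 with an estimated correlation), sterol synthesis (0.92, 3.5e-06 and 0.060), hypoxia and HIF targets (1.07, 8.5e-06 and 0.092), MYC and ribosome biogenesis (0.62, 1.4e-05 and 0.054), fatty acid synthesis (0.76, 0.0018 and 0.18) and epithelial junctions and keratins (-0.32, 0.040 and 0.28) passed camera only. With fry 19, 16 and 20 of 22 lists passed for PC3 against LNCaP, C42B against LNCaP and PC3 against C42B. In simulated interactions 17.9% (PC3 against LNCaP), 9.68% (C42B against LNCaP) and 5.00% (PC3 against C42B) of calls were unchanged genes. Only 200 genes were changed in these simulations, so the shares cannot be carried over to the real counts. Run date went with the line in each interaction. Dose and plating density also differed between PC3 and LNCaP, medium and plating density between C42B and LNCaP, and dose and medium between PC3 and C42B, and none of these can be separated from the line.

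**Figure D3:**
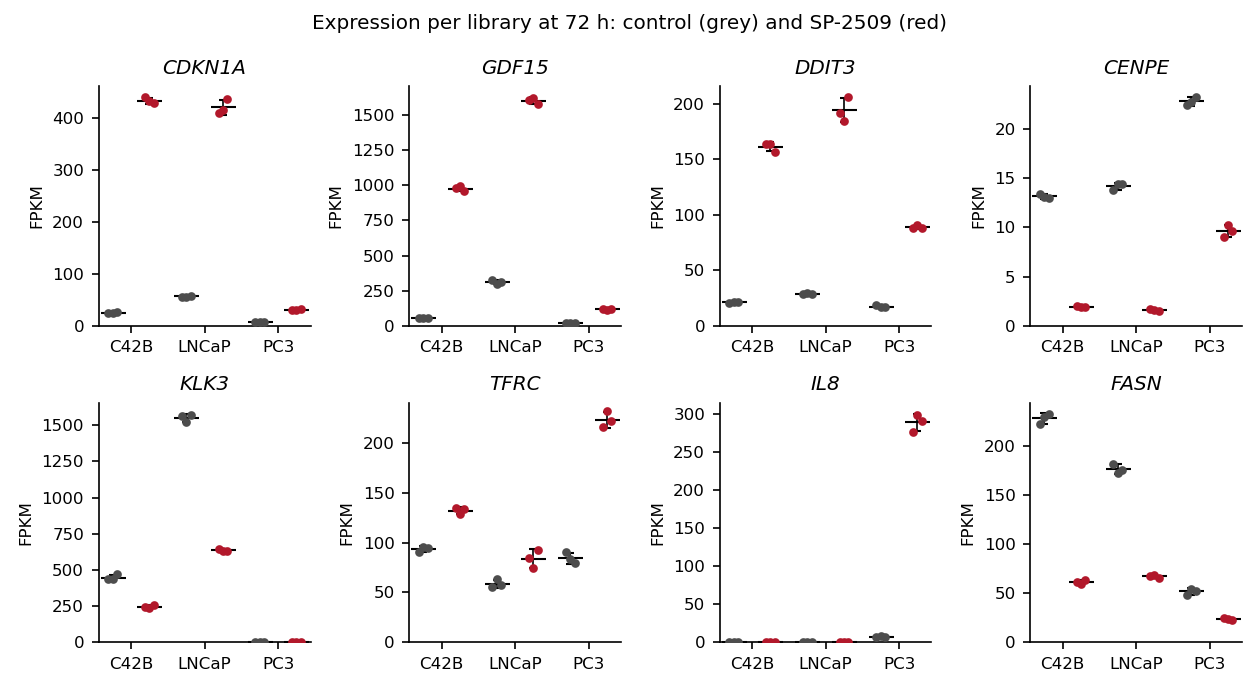
FPKM of 8 genes in each library at 72 h (points), with mean and SD over 3 libraries, for control (grey) and SP-2509 (red) in C42B, LNCaP and PC3. CDKN1A, GDF15 and DDIT3 were higher and CENPE and FASN lower in treated libraries of every line.

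The last comparison asked what had changed in LNCaP after 24 h of 1 µM SP-2509. GDF15 (chromosome 19, 18374731 to 18389176 in GRCh38) rose from 81.7 ± 1.93 to 578 ± 24.9 CPM (2.82 ± 0.043, edgeR adjusted p = 1.5e-35) and DDIT3 from 12.1 ± 1.72 to 65.0 ± 4.55 CPM (2.44 ± 0.075, edgeR adjusted p = 6.0e-25). CDKN1A (chromosome 6, 36676460 to 36687339) rose from 209 ± 8.06 to 643 ± 15.3 CPM (1.62 ± 0.039). PLK1 (chromosome 16, 23677656 to 23690367) fell from 110.0 ± 4.204 to 37.1 ± 2.48 CPM (-1.58 ± 0.052), and DHRS2, a short-chain dehydrogenase (chromosome 14, 23630115 to 23645639), fell from 13.1 ± 1.92 to 2.38 ± 0.320 CPM (-2.44 ± 0.14).

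All 34 mitosis and kinetochore genes had fallen by 24 h, with a mean of -0.83 (camera adjusted p = 3.3e-67, and 0.013 with an estimated correlation). Among them were KIF20A (-1.41 ± 0.053), CDC20 (-1.39 ± 0.055) and CENPE (-0.94 ± 0.051). In MYC and ribosome biogenesis 18 of 21 genes fell, or 19 adjusted over the list alone (mean -0.42, camera adjusted p = 8.5e-18, and 0.033 with an estimated correlation). NOP16 was at -0.83, NOP56 at -0.74 and PA2G4 at -0.58. Heat shock genes fell in 9 of 11 cases and rose in 1 (mean -0.45, camera adjusted p = 8.3e-12, and 0.013 with an estimated correlation). Among them were the chaperones HSPH1 (-0.94) and DNAJA1 (-0.71) and HSPA1B (-0.81), the last uncertain because of its copy HSPA1A. DNA replication and E2F targets fell in 24 of 30 cases, or 26 adjusted over the list alone (mean -0.38, camera adjusted p = 9.9e-15, adjusted p = 0.064 with an estimated correlation). MCM5 was at -0.91, MCM6 at -0.78 and MCM10 at -0.64. Homologous recombination repair had 9 falls among 16 genes, and adjusted over the list alone 9 falls and 1 rise (mean -0.19, camera adjusted p = 0.017, adjusted p = 0.22 with an estimated correlation). EXO1 was at -0.58, RAD51AP1 at -0.43 and RAD54L at -0.38. Sterol synthesis genes fell in 18 of 19 cases and rose in 1 (mean -0.46, camera adjusted p = 3.1e-13, adjusted p = 0.055 with an estimated correlation). SQLE was at -0.72 and DHCR7 at -0.58. Fatty acid synthesis had 9 falls and 2 rises among 12 (mean -0.35, camera adjusted p = 8.6e-09, adjusted p = 0.079 with an estimated correlation). ELOVL6 was at -1.12, FASN at -0.89 and SREBF1 at -0.51.

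In the ATF4 and integrated stress response list 22 of 23 genes rose by 24 h (mean 0.92, camera adjusted p = 2.4e-58, and 0.0097 with an estimated correlation), CHAC1, which degrades glutathione, at 1.78 and ATF3 at 1.71. Of p53 targets 19 of 22 rose (mean 0.74, camera adjusted p = 2.3e-37, and 0.011 with an estimated correlation), TP53I3 at 1.72. Hypoxia and HIF targets had 16 rises and 1 fall among 21, with 2 falls adjusted over the list alone (mean 0.46, camera adjusted p = 1.5e-15, and 0.041 with an estimated correlation). Among them were VEGFA (1.26), P4HA2 (0.98) and ALDOC (0.91). Lysosome and autophagy genes rose in 11 of 14 cases and fell in 1 (mean 0.24, camera adjusted p = 2.2e-04, and 0.045 with an estimated correlation). MAP1LC3B was at 0.78, WIPI1 at 0.61 and SQSTM1 at 0.55. The apoptosis BCL2 family had 7 rises and 1 fall among 12 genes, or 2 falls adjusted over the list alone (median 0.23, mean 0.70, camera adjusted p = 0.0012, adjusted p = 0.055 with an estimated correlation). BMF was at 1.19 and PMAIP1 at 1.11. The mean of this list was raised by HRK (4.43 ± 0.62), which rose from 2 counts in the 3 controls together to 50 in the treated libraries, a ratio of 25.5 by depth with a 95% counting interval of 6.70 to 216. For the passing lists not given a second count here, the counts adjusted over the list alone were the same. Members that moved against their lists were SLC2A1 (-0.18), SC5D (0.47), ELOVL5 (0.19), ACSL1 (0.10), GLA (-0.29), HSPA4L (0.18) and BAK1 (-0.32). Other large rises were those of the collagen COL16A1 (3.27 ± 0.22), the keratin KRT80 (2.61 ± 0.19), NOS3 (2.35 ± 0.14) and the fucosyltransferase FUT3 (2.28 ± 0.18), and the helicase PIF1 (-1.53 ± 0.13) and PSRC1 (-1.24 ± 0.089) fell. KDM1A fell by 0.43 ± 0.046, KLK3 (chromosome 19, 50854915 to 50860764) by 0.18 ± 0.038 and MYC by 0.27 ± 0.042, and TFRC (chromosome 3, 196027183 to 196082189) rose by 0.50 ± 0.042 and ZNF217 by 0.14 ± 0.037. HMOX1 did not pass (-0.10 ± 0.12, edgeR adjusted p = 0.54).

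Lists that did not pass camera at 24 h were endoplasmic reticulum chaperones (adjusted p = 0.062), iron homeostasis (0.13), NF-kB and inflammatory cytokines (0.33), the LSD1 complex (0.34), interferon response (0.34), mitochondrially encoded genes (0.39), androgen response (0.72), mesenchymal genes (0.78), NRF2 targets (0.86) and epithelial junctions and keratins (0.86). The median and mean differed in sign for chaperones (-0.06 and 0.10, test up), the LSD1 complex (0.02 and -0.02, test down) and NRF2 targets (-0.12 and 0.03, test down), and the epithelial list had a median of -0.01 beside a test direction of up. With fry 17 of 22 lists passed. Metallothioneins and the pluripotency, neuroendocrine, immune cell, fibroblast and endothelial lists had fewer than 5 tested genes. EdgeR called 6839 of 15209 genes tested, 3328 higher and 3511 lower, of which 283 and 50 changed at least 2-fold, and 51.6% of genes had no overlap between treated and control libraries.

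The 2 LNCaP times were compared by counting calls over 11274 genes tested at both, with no test of the difference. The cells were plated at 400000 per well for 24 h and 350000 for 72 h. PLK1 was lower at 24 h (-1.58) and 72 h (-3.255), and CDKN1A rose by 1.62 and 2.87. LDHA was higher at 24 h (0.41) and lower at 72 h (-0.997). Genes called higher at both times numbered 1580, where independent lists would share 673.2, and 2410 were lower at both, where 1274.2 would be shared. Genes higher at 24 h and lower at 72 h numbered 282, and 112 went the other way. Across genes the fold changes correlated with r = 0.65 (rho = 0.62). Of 522 genes changed at least 2-fold at 72 h, 504 had the same sign at 24 h and 448 were called in the same direction. These genes were chosen by their size at 72 h, so their sizes at the 2 times are not compared.

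**Figure D4:**
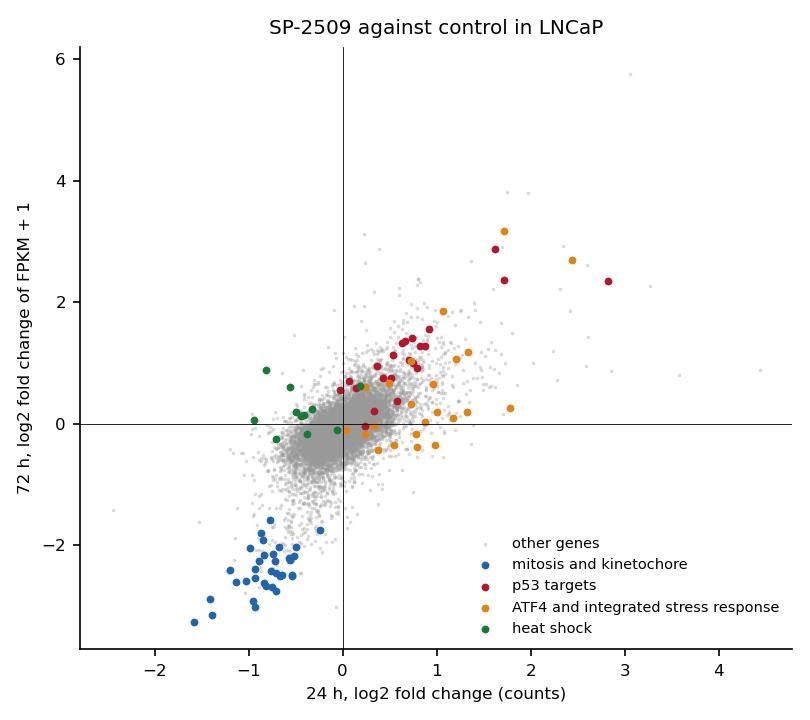
Log2 fold change per gene in LNCaP at 24 h (counts) and 72 h (FPKM + 1), with 4 gene lists coloured. Mitosis and kinetochore genes had a mean of -0.83 at 24 h and -2.41 at 72 h, and heat shock genes -0.45 and 0.27.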

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

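Chosen only after the results were seen were the test of all mitochondrial transcripts, the look at mitochondrial tRNAs, the tests of scaling and the comparison of starting levels. The splits of libraries, the transcripts without poly(A) tails, the members near the floor and the dose were written down before. SEs of list means in this part are taken across genes, which are not independent replicates, so they can understate the uncertainty.

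In LNCaP at 24 h the mitochondrial ribosomal RNAs MT-RNR1 (1.41 ± 0.048) and MT-RNR2 (1.13 ± 0.041) were higher in treated libraries. A larger share of RNA without poly(A) tails could not be tested with the fixed list, because 0 of its 21 transcripts had enough counts. Of the mitochondrial tRNAs tested, MT-TQ (-0.76 ± 0.13), MT-TS1 (-0.71 ± 0.18) and MT-TP (-0.67 ± 0.24) were called lower. MT-TI (-0.42), MT-TA (-0.22) and MT-TT (0.39) were not called. These tRNAs were singled out after their values were seen, so they cannot decide whether such RNA rose in general. A rise of all mitochondrial transcripts does not account for the higher MT-RNR1 and MT-RNR2. The 13 protein-coding mitochondrial genes had a mean log2 fold change of 0.045 (SE 0.062), and the highest, MT-ND4L, was at 0.45. Whether the treatment or the library preparation raised MT-RNR1 and MT-RNR2 remains open.

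Hypoxia and HIF targets rose more in PC3 than in LNCaP at 72 h, by a mean of 1.14 (camera adjusted p = 2.1e-07, and 0.063 with an estimated correlation, which loses the call). With median-ratio scaling the difference was 1.14 (SE 0.21, 23 genes). This scaling moved the median difference over all genes by only -0.0077, so it was a weak test of scaling. Members near the floor in LNCaP do not account for the difference, since the 15 members at 5 FPKM or more in LNCaP controls gave 1.03 (SE 0.18). The dose was higher in 1 line only, so dose, plating density and line cannot be told apart.

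The androgen response list fell in LNCaP and not in C42B at 72 h, a mean difference of 0.44, and the fall in LNCaP had a camera adjusted p = 4.4e-04, and 0.27 with an estimated correlation, which loses the call. Its genes started lower in C42B controls, with a mean log2 ratio to LNCaP controls of -1.15 (SE 0.21, 24 genes), so a lower starting level is a possible explanation. With median-ratio scaling the difference was 0.43 (SE 0.11, 24 genes), but this scaling moved the median difference over all genes by only 0.0019. It was therefore a weak test of scaling. The medium, the plating density and the line itself cannot be told apart.

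In each of the 4 comparisons with control the real grouping gave the most genes, 1 of 10 splits, and the highest other split gave 0 in C42B, 1 in PC3, 1 in LNCaP at 72 h and 0 at 24 h, too few splits for a share below 0.05. In each interaction only 1 of 100 splits, the real one, reached the real count. The highest other split gave 5280, 3107 and 5003 genes for PC3 against LNCaP, C42B against LNCaP and PC3 against C42B. Those splits kept the real labels of 1 line. Mixing labels within a line removes its treatment effect, so the splits do not test whether the lines responded alike.

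The responses of PC3 and LNCaP differed for 9072 genes, among them IL8 (4.89), CASP14 (2.72), TNFAIP3 (3.06), PODXL (2.30), NUSAP1 (2.49), LINC00261 (-3.03), PHACTR3 (-3.84), GALNT10 (-2.39), COL2A1 (-2.43), NBPF1 (-2.25), KDM1A (0.64), KLK3 (1.54), CENPE (1.37), MYC (2.90), CDKN1A (-0.85), ZNF217 (-0.46), TFRC (0.89) and DDIT3 (-0.40). KLK3 lay below the filter in PC3, and IL8, CASP14, TNFAIP3, LINC00261, PHACTR3 and COL2A1 in LNCaP, so these values mainly restate the change in the other line. With camera they differed for lists that also held with an estimated correlation, mitosis and kinetochore (1.92), DNA replication and E2F targets (1.38), metallothioneins (1.57) and NF-kB and inflammatory cytokines (1.73). Most NF-kB members lay below the filter in LNCaP. The calls of other lists were lost with an estimated correlation, whose adjusted p follows the mean difference: homologous recombination repair (1.08, 0.063), androgen response (0.59, 0.11), MYC and ribosome biogenesis (0.50, 0.063), p53 targets (-0.80, 0.063), ATF4 and integrated stress response (0.40, 0.27), hypoxia and HIF targets (1.14, 0.063), sterol synthesis (0.48, 0.15), fatty acid synthesis (0.41, 0.28), mesenchymal (0.54, 0.12) and heat shock (-0.54, 0.063).

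The responses of C42B and LNCaP differed for 4698 genes, among them C11orf92 (3.219), CHST2 (2.47), THBS1 (1.95), CALCA (2.32), LPL (1.64), THOP1 (-1.36), MYLK (-2.19), RAP2B (-1.30), NUCB2 (-0.85), HNRPDL (-0.70), KLK3 (0.42), CENPE (0.27), MYC (0.26), CDKN1A (1.17), ZNF217 (0.78) and HMOX1 (-0.45). CHST2, CALCA and LPL lay below the filter in LNCaP. The call of KLK3 was lost in 11 of 12 fits without a library and in 3 other alternatives, among them a pseudocount of 0.1 (limma adjusted p = 0.51), and that of MYC with the replicate block (0.050) and without either of a pair of libraries (0.051 and 0.056). KLK3 kept its call in the fit on the C42B and LNCaP libraries alone. With camera they differed for lists that also held with an estimated correlation, androgen response (0.44), p53 targets (0.45), ATF4 and integrated stress response (0.46), endoplasmic reticulum chaperones (0.27), NRF2 targets (-0.49), sterol synthesis (-0.44) and heat shock (-0.45). The calls of other lists were lost with an estimated correlation, whose adjusted p follows the mean difference: mitosis and kinetochore (0.23, 0.12), MYC and ribosome biogenesis (-0.11, 0.27), metallothioneins (-0.32, 0.12), fatty acid synthesis (-0.35, 0.051), mesenchymal (0.20, 0.12) and apoptosis BCL2 family (0.25, 0.12).

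The responses of PC3 and C42B differed for 9701 genes, among them IL8 (5.11), TNFAIP3 (3.33), CASP14 (2.71), KRT81 (3.03), KRT86 (2.64), C11orf92 (-4.46), CHST2 (-3.49), LINC00261 (-3.03), GPNMB (-5.14), PHACTR3 (-3.90), KDM1A (0.66), KLK3 (1.13), CENPE (1.10), MYC (2.64), CDKN1A (-2.02), ZNF217 (-1.24), TFRC (0.90) and DDIT3 (-0.57). IL8, TNFAIP3, CASP14, KRT81, KRT86, LINC00261 and PHACTR3 lay below the filter in C42B, and C11orf92, GPNMB and KLK3 in PC3. With camera they differed for lists that also held with an estimated correlation, mitosis and kinetochore (1.69), DNA replication and E2F targets (1.42), p53 targets (-1.247), metallothioneins (1.89) and NF-kB and inflammatory cytokines (1.72). Most NF-kB members lay below the filter in C42B. The calls of other lists were lost with an estimated correlation, whose adjusted p follows the mean difference: homologous recombination repair (0.99, 0.085), MYC and ribosome biogenesis (0.62, 0.054), hypoxia and HIF targets (1.07, 0.092), sterol synthesis (0.92, 0.060), fatty acid synthesis (0.76, 0.18) and epithelial junctions and keratins (-0.32, 0.28).

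LDHA was at 0.41 at 24 h and -0.997 at 72 h in LNCaP, and HSPA1B at -0.81 and 0.89, with no test of the difference. The share of uniquely mapped 24 h reads in no feature was 13.0% in treated and 12.6% in control libraries, and the multimapping share of all reads 3.78% and 3.70%.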

How the results depend on the processing

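Triplicate wells are not stated to be separate experiments, so n counts libraries, and the 72 h FPKM state no count uncertainty. With a minimum change of 2-fold 791, 592, 565 and 333 genes remained in C42B, PC3, LNCaP at 72 h and LNCaP at 24 h, with 41 higher and 11 lower in all 3 lines and 65 higher and 14 lower at both times. With an estimated correlation 0, 2, 0, 7, 4, 7 and 5 lists passed in C42B, PC3, LNCaP at 72 h, LNCaP at 24 h, PC3 against LNCaP, C42B against LNCaP and PC3 against C42B. Interactions were fitted on all 72 h libraries and each line on its own, so these counts do not rank the comparisons. In C42B all 22 p53 targets rose by a mean of 1.58, with an estimated correlation of 0.11 and a camera adjusted p = 0.10. In C42B against LNCaP their mean difference was 0.45, with 0.20 and 0.037. A call lost in a single line is therefore not a weaker change than a call kept in an interaction. With a pseudocount of 0.1 FPKM 4 list calls were lost: the apoptosis BCL2 family in PC3 (camera adjusted p = 0.052) and in C42B against LNCaP (0.052), metallothioneins in C42B against LNCaP (0.051) and mesenchymal genes in PC3 against LNCaP (0.21), the cause was not tested. Replicate numbers were not shown to pair samples, and with them as a block the same 7 counts of genes were 9079, 8906, 6962, 7193, 8596, 3866 and 9276. DESeq2 called 5293 genes at 24 h. With median-ratio scaling 1414 genes were higher and 1488 lower in all 3 lines, and 1801 higher and 2156 lower at both times. Leaving out any 1 library gave 8633 to 8953 genes in C42B, 8132 to 8772 in PC3, 6569 to 7899 in LNCaP at 72 h and 5852 to 6869 at 24 h. Of 3949 alternatives for the genes named here without a minimum change, 3912 left the call unchanged and 37 changed it. Apart from the 10 fixed genes, these were named for the size or adjusted p of their change in the same data. Their calls could therefore hardly change, and the share does not describe the other called genes. Alternatives in which a gene was no longer tested were not counted. KLK3 in C42B against LNCaP lost its call with a pseudocount of 0.1 (limma adjusted p = 0.51), without a filter (0.072) and with small RNAs kept (0.057), and MYC lost its call with the block (0.050), the cause was not tested. The fit on the C42B and LNCaP libraries alone, without PC3, kept the call of KLK3.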

Other observations

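The gene families here were chosen by symbol after the values had been seen, and none of these results was planned. Histone genes were higher in 30 and lower in 6 of 46 cases in C42B (camera adjusted p = 4.8e-06, and 0.031 with an estimated correlation), 36 and 2 of 50 in PC3 (5.3e-09, 0.052) and 21 and 3 of 45 in LNCaP at 72 h (5.9e-05, 0.10), with HIST1H2BD at 1.247, 1.72 and 0.99. At 24 h 11 of 27 were higher and 4 lower (limma camera adjusted p = 0.12). Some histone transcripts lack poly(A) tails and have close copies, so single values are uncertain.

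No call of the hnRNP or SR families held with an estimated correlation. Among 18 hnRNP genes 17 were lower in C42B (camera adjusted p with an estimated correlation = 0.12), 16 in PC3 (0.27), 15 in LNCaP at 72 h (0.062) and 16 at 24 h (0.13), with HNRNPA2B1 at -1.48, -0.86, -1.14 and -0.45. Among 11 SR splicing factors the counts lower were 10, 11, 9 and 7 (camera adjusted p with an estimated correlation = 0.099, 0.11, 0.32 and 0.055), with SRSF2 at -1.38, -0.42, -1.15 and -0.94.

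Mitochondrial ribosomal genes were lower in 69 of 76 cases in C42B, 59 of 76 in LNCaP at 72 h and 56 of 75 at 24 h (camera adjusted p with an estimated correlation = 0.12, 0.32 and 0.055), while in PC3 29 were higher and 22 lower (limma camera adjusted p = 0.46). Proteasome genes were lower in 33 of 36, 25 of 37 and 28 of 36 cases in the same order (camera adjusted p with an estimated correlation = 0.15, 0.55 and 0.055), and tubulins in 15 of 15, 11 of 14 and 7 of 13 (0.031, 0.070 and 0.18), with TUBA1B at -2.07, -1.57 and -0.36. Neither proteasome genes (limma camera adjusted p = 0.70) nor tubulins (0.43) passed in PC3, where the medians of these 3 families changed sign with median-ratio scaling. Cytosolic ribosomal protein genes were higher in 75 of 79 cases in PC3 (camera adjusted p = 4.5e-15; 0.11 with an estimated correlation) and in 18 of 81 in C42B, with 11 lower (camera adjusted p = 0.031, and 0.66 with an estimated correlation). With median-ratio scaling 34 were higher and 7 lower in C42B. In LNCaP 15 were higher and 7 lower of 81 at 72 h (limma camera adjusted p = 0.064), or 25 and 6 with median-ratio scaling, and 14 and 7 of 79 at 24 h (limma camera adjusted p = 0.28).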
